A study of Mus musculus with 2 samples.

How the data were processed

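H3K9me3 was measured by chromatin immunoprecipitation and sequencing in kidneys of B6NCrl mouse embryos at 15.5 days, in 2 pools of embryos of both sexes. Per the labels, biological replicate 1 came from 78 embryos and replicate 2 from 62, and each was sequenced as 2 technical replicates that were combined. Groups and replicate numbers were taken from the labels, which put both samples in 1 group. The 4 peak lists used here were deposited as narrowPeak tables on mm10. Per the deposited readme texts, each replicate's list came from that replicate's alignments and a control file of its own, the pooled list from the alignments and controls of both, and the replicated list from the other 3 lists, by a rule that is not stated. The peak caller, its threshold, the aligner and the read depth are not given in the sources used here, and the controls and signal tracks were not analysed here.

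The fold enrichment in column 7 of each deposited list is a ratio of immunoprecipitated over background signal that the authors' peak caller gave each peak, and its scaling is not stated. The −log10 p and −log10 q in columns 8 and 9 were likewise deposited by the authors for each peak. All lists began at a −log10 p just above 2, and −log10 q went down to 0 in the replicate lists, so these lists hold many peaks that a stricter threshold would drop. At q of at most 0.05, 36.7% of replicate 1 peaks, 55.2% of replicate 2 peaks, 65.3% of pooled peaks and 96.6% of replicated peaks stayed. These values were used to rank or filter peaks within a list. Medians and single values are also given as descriptions, without a test. Because each replicate was called against its own control at an unknown depth, a peak missing from one list does not show that the mark was absent there.

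Peaks on the 21 assembled chromosomes (1 to 19, X and Y) were analysed, and peaks on other scaffolds were left out because rotation needs an ordered sequence. Positions were matched to the mouse reference GRCm38, which is the same assembly as mm10, and to its GENCODE annotation, and chromosome names matched, with no peak past a chromosome end. Runs of at least 1000 unknown bases were removed, leaving 2648 Mb of sequence laid end to end. The reference for every overlap test was random rotation, in which all peaks of a list were shifted by the same random offset along this sequence, so that peak lengths, spacing and clustering were kept. Overlap of the replicate lists was tested with 1000 rotations and a minimum overlap of 1 bp (one-sided permutation p). Annotation classes were assigned in the order promoter, exon, intron and intergenic sequence, and tested with 1000 rotations (two-sided permutation p). Promoters were 1 kb on each side of the start of any transcript of a protein-coding gene. Intergenic sequence was all sequence outside protein-coding genes and these promoters, so other annotated genes fell into it. The transcription start windows used for gene lists were instead set on the outermost 5′ end of each gene. For gene lists, a gene was counted when a replicated peak overlapped its body extended by 1 kb on each side, and 10000 rotations gave two-sided permutation p values that were adjusted by the Benjamini-Hochberg method over the 22 lists. The smallest two-sided permutation p these can give is 0.0002. First and last exons of zinc finger genes were taken from the transcript with the longest coding sequence and compared by the two-sided exact McNemar test. Chromosome ranks were compared by Spearman's rho with 100000 resamples. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only and treat peaks as independent. Replicate values are given as mean ± SD over 2 lists, and this spread rests on 2 pools only.

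The tests, their alternatives, the gene lists and the rule for named genes were chosen before the data were examined. The rule took the 25 protein-coding genes (without provisional Gm and Rik models) whose bodies held the most bases of replicated peaks that were also overlapped in each replicate list. It further took up to 4 members of each gene list with the most such bases and, where under 50% of a list had a peak, up to 2 members without one. The 10 replicated peaks of highest fold enrichment, the 10 longest runs of peaks and the 10 most covered 1-Mb windows were also taken, and the text names those with the highest values. Of 42 symbols in the imprinted list, 36 are protein-coding genes in the annotation. Of 36 in the pluripotency and 2-cell list, 34 matched. The zinc finger, olfactory and vomeronasal lists, among others, were built from symbol patterns, and 7 zinc finger genes also belong to another list.

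Alternatives were an overlap of at least 50% of either peak, peaks with q of at most 0.05, the 20000 peaks of highest −log10 p, peaks within 1 kb merged, shuffling within chromosomes in place of rotation, peaks per Mb, peak midpoints, promoters and transcription start windows of 2 kb on each side, at least 500 bp of peak in a gene, the pooled list, length-matched random genes, windows of 500 kb, merging gaps of 1 and 10 kb, and each replicate list without the other. After the data were examined, 2 alternatives were added for gene lists. The first kept only replicated peaks in which at least 90% of 32-bp words, sampled every 10 bp, occurred once in the assembled chromosomes on either strand, which left 9619 peaks. The second joined members within 100 kb into 1 locus.

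The tests were tried on simulated peaks with known answers. With 20% of 10000 peaks planted in a second list, the overlap test recovered 19.9% over random placement, and it called 2 of 20 unrelated pairs of lists at 0.05. With peaks planted in 14 germline genes, the gene list test called that list in 19 of 20 runs, and it called no list in 20 runs without planted peaks. Germline genes lie more than 100 kb apart, so the planted runs do not show how well tandem families are called. With 500 peaks planted on exons, the annotation test called the exon excess in 20 of 20 runs, and in 1 of 20 without. Peaks placed on the last exon of 211 zinc finger genes were counted on the last exon in all 211 and on the first exon in 0. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.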

Results

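Trimethylation of lysine 9 on histone H3 (H3K9me3), a mark of silenced chromatin, was mapped by chromatin immunoprecipitation and sequencing in kidneys of B6NCrl mouse embryos at 15.5 days of development. The labels put both samples in 1 group, with 2 biological replicates and no treatment or second tissue. Replicate 1 was a pool of kidneys from 78 embryos and replicate 2 a pool from 62 embryos, and both pools held males and females. Peaks were listed for each replicate, for the replicates pooled, and as a replicated list of the whole series, on mouse build mm10. Replicate 1 had 39233 peaks covering 9.92 Mb, and replicate 2 had 35380 peaks covering 9.49 Mb. The pooled list had 64919 peaks covering 19.6 Mb, and the replicated list 14160 peaks covering 7.46 Mb. Median peak length was 210.5 bp ± 3.54 (SD, n = 2) in the replicate lists and 423 bp in the replicated list. Read depth is unknown from these lists, so no precision of the signal itself can be given, and intervals below cover counting error only. Single lists of the whole series have no replicates. The design leaves 1 question between samples, which regions carried the mark in both pools, and several within the genome, namely which chromosomes, gene classes and gene families carried it.

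The same regions were marked in both pools far more often than random placement gives, but most single peaks of either replicate had no counterpart in the other. On the 21 assembled chromosomes, 25.7% of replicate 1 peaks (9982 of 38872; exact 95% binomial interval 25.2 to 26.1%) overlapped a replicate 2 peak by at least 1 bp. In the other direction the share was 27.8% (9746 of 35010; 27.4 to 28.3%). Peaks rotated together along the chromosomes overlapped in 0.659% and 0.733% of cases on average, and never in more than 1.09% and 1.20%. Covered bases shared by both replicates made up 13.2% of the bases covered by either, against 0.178% after rotation, a 73.7-fold excess (one-sided permutation p = 0.000999, the smallest that 1000 rotations can give). Of the peaks without an overlap, 37.7% in replicate 1 and 45.3% in replicate 2 lay within 5 kb of a peak of the other replicate, where rotation gave 9.22% and 10.8% (one-sided permutation p = 0.000999 for both, the smallest possible). This distance was chosen after the data were examined.

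Peaks of the highest fold enrichment recurred most often. Fold enrichment is the authors' own value for each peak, and the deciles only rank peaks within a list. In the top decile, 55.7% of replicate 1 peaks (95% interval 54.1 to 57.2%) and 57.5% of replicate 2 peaks (55.9 to 59.2%) were overlapped by the other replicate. In the lowest decile the shares were 22.9% and 25.4%. Shares did not rise steadily below the top decile, and many peaks of the middle deciles had tied fold values. The lowest decile was above deciles 2, 3, 4 and 6 in replicate 1, and above deciles 2 to 6 in replicate 2. Below the top decile, shares ran from 14.2% in decile 4 to 32.9% in decile 9 of replicate 1. In replicate 2 they ran from 16.2% in decile 2 to 35.8% in decile 9.

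**Figure D1:**
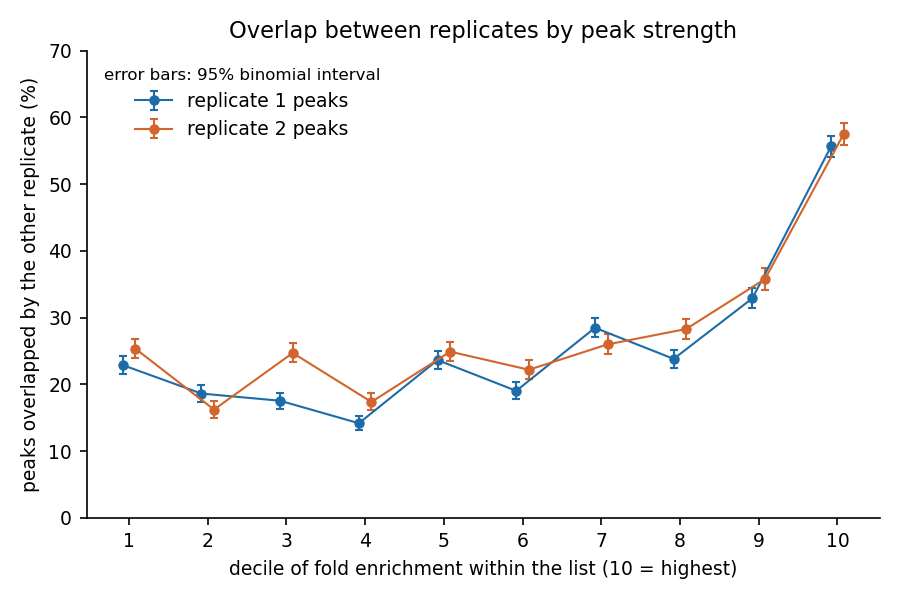
Percent of peaks overlapped by the other replicate (y axis) in each decile of fold enrichment within a list (x axis), with exact 95% binomial intervals as error bars, for replicate 1 (blue) and replicate 2 (orange). Both lines stay below 36% through decile 9 and reach 55.7% and 57.5% in decile 10.

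All 14160 replicated peaks were also present in the pooled list with identical coordinates, and made up 21.5% of its peaks on assembled chromosomes. Of these pooled peaks, 14.4% (exact 95% interval 14.1 to 14.7%) overlapped a peak in each replicate list over at least 50% of either peak, and all 9283 of them were in the replicated list. A further 4622 replicated peaks did not meet that overlap in both lists, and 4538 did not have even a 1 bp overlap in both. The rule that made the replicated list is not stated, so a replicated peak was not always one called in each pool. No peak of either replicate overlapped 35.2% of pooled peaks at all. Replicated peaks were longer than other pooled peaks, with medians of 422 and 211 bp, and had a higher median fold enrichment, 3.55 against 2.88. Their median −log10 q was 3.39 against 1.43.

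Chromosomes 7 and 17 carried the most H3K9me3 peaks for their size, and the sex chromosomes the least. This ranking is of called peaks. Neither how uniquely reads can be placed nor the copies of X and Y in pools of both sexes was taken into account. Few called peaks therefore do not show that the sex chromosomes carried little of the mark. Replicated peaks covered 0.684% of chromosome 7 and 0.574% of chromosome 17, which was 2.50 and 2.10 times the share over all assembled chromosomes. In the replicate lists, coverage was 0.776% ± 0.0217 (SD, n = 2) for chromosome 7 and 0.682% ± 0.00145 (SD, n = 2) for chromosome 17. Chromosomes 4 and 18 followed, at 0.465% ± 0.00921 and 0.450% ± 0.00874 (SD, n = 2). Chromosome 14 had the lowest coverage among autosomes, 0.237% ± 0.0125 (SD, n = 2), and the X chromosome had 0.145% ± 0.0322 (SD, n = 2). The Y chromosome had 15 peaks in replicate 1 and 18 in replicate 2, at 0.00788% ± 0.00285 of its sequence (SD, n = 2). The order of the 21 chromosomes was nearly identical in both pools (Spearman's rho = 0.994, Pearson's r = 0.996, permutation p = 1e-05 for each, the smallest that 100000 resamples can give). Without the 2 chromosomes farthest from the median, rho was 0.991 and r 0.996. X chromosome coverage was 0.168% in replicate 1 and 0.122% in replicate 2, a ratio of 0.729 where autosomes ran from 0.883 to 1.03. The Y chromosome, with few peaks, had a ratio of 1.69.

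**Figure D2:**
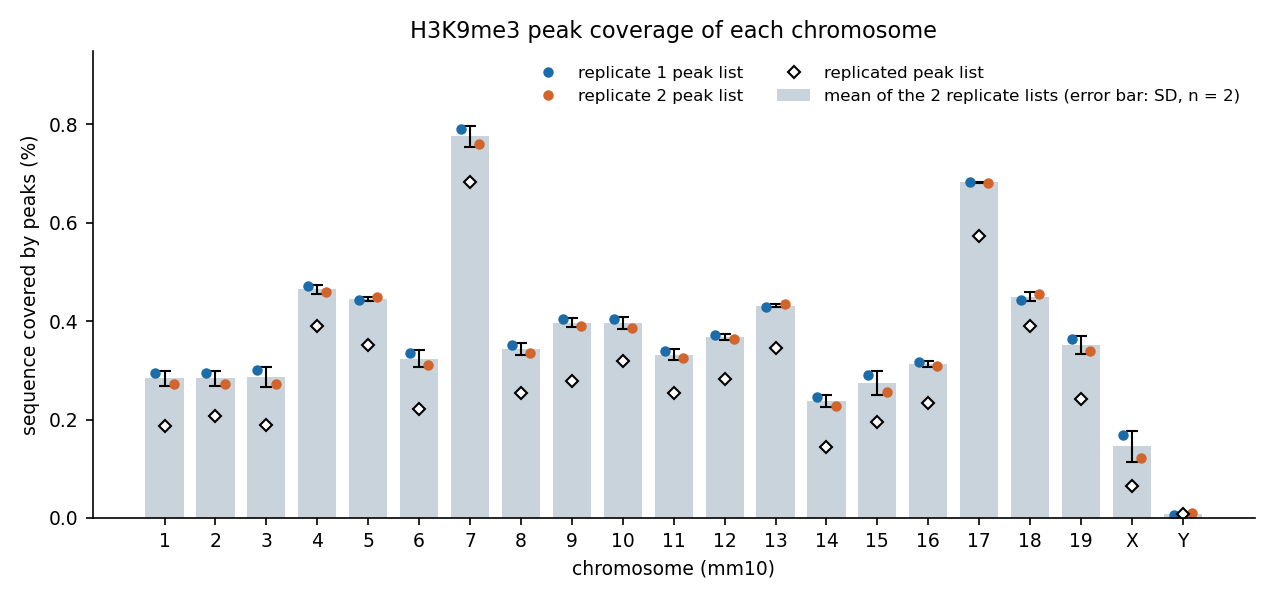
Percent of each mm10 chromosome's sequence covered by peaks (y axis) for chromosomes 1 to 19, X and Y (x axis), with bars for the mean of 2 replicate lists, error bars for their SD, blue and orange points for each replicate and diamonds for the replicated list. Chromosomes 7 and 17 stand highest, at means of 0.776% and 0.682%, and X and Y lowest, at 0.145% and 0.00788%.

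Exons held more of the mark, and introns less, than their share of the genome. Exons of protein-coding genes outside promoters made up 6.66% of replicated peak bases and 2.64% of the assembled genome, a 2.52-fold excess, and rotations gave 2.17 to 3.14% in their central 95% (two-sided permutation p = 0.002, the smallest that 1000 rotations can give). Introns made up 26.9% of peak bases against 33.6% of the genome, 0.801-fold (two-sided permutation p = 0.002, again the smallest possible). Promoters, taken as 1 kb on each side of any transcript's start, held 4.21% of peak bases against 3.70% of the genome (two-sided permutation p = 0.142). In each replicate list alone they held 3.50%, 0.945 times the genome's share (two-sided permutation p = 0.456 in replicate 1 and 0.507 in replicate 2). Intergenic sequence, here all sequence outside protein-coding genes and their promoters, held 62.2% against 60.1% (two-sided permutation p = 0.304). In the replicate lists, exons held 5.02% ± 0.295 and introns 27.0% ± 0.121 of peak bases (SD, n = 2). The intergenic excess passed the threshold in each replicate list alone, at 1.07 and 1.08 times the genome's share (two-sided permutation p = 0.022 and 0.012).

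Among 21911 protein-coding genes, 2580 (11.8%) had a replicated peak in the gene or within 1 kb of it. Of the 22 gene lists, 5 had more genes with a peak than rotations gave after Benjamini-Hochberg adjustment: zinc finger genes, clustered protocadherins, vomeronasal receptors, imprinted genes and germline genes. No list had fewer, though for many lists rotations gave too few marked genes for fewer to be detected. The 6 lists with an unadjusted permutation p under 0.05 all had more, the additional one being cytochrome P450 genes.

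**Figure D3:**
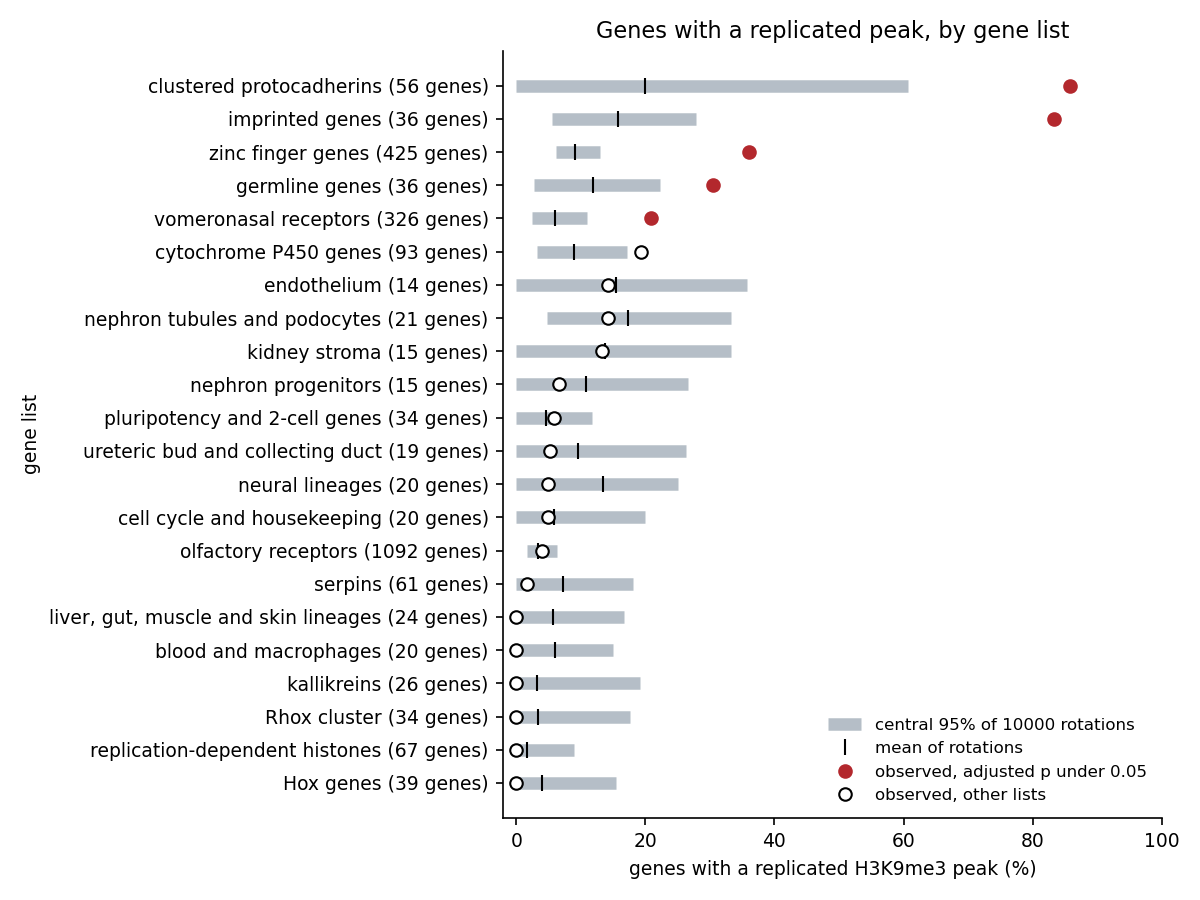
Percent of the genes of each list with a replicated peak (x axis) for 22 gene lists (y axis), as circles, filled red where the adjusted permutation p was under 0.05, over grey bars for the central 95% of 10000 rotations and ticks for their mean. Clustered protocadherins and imprinted genes stand farthest right, at 85.7% and 83.3%.

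Zinc finger genes, many of which encode DNA-binding repressors of the KRAB family, carried a peak more often than rotations gave. A replicated peak lay in 153 of 425 (36%), against 38.9 on average after rotation, a 3.94-fold excess (adjusted two-sided permutation p = 0.0022). In the replicate lists alone, 45.6% ± 0.998 of them had a peak (SD, n = 2), but the excess over rotations was smaller, 2.06-fold in replicate 1, 2.30-fold in replicate 2 and 1.89-fold in the pooled list. Zfp981 (ENSMUSG00000056300.14, chromosome 4, 146502027 to 146539395) held 25 replicated peaks, and its peak bases found in the replicate lists came to 13.6 kb ± 0.409 (SD, n = 2). Zfp873 on chromosome 10 (82048123 to 82064745) held 12.5 kb ± 0.329, Zfp110 on chromosome 7 (12834761 to 12850577) 10.9 kb ± 1.16, and Zfp930 on chromosome 8 (69209038 to 69230536) 10.7 kb ± 2.15 (SD, n = 2 for each). Members without a replicated peak included Prdm9, which directs recombination in meiosis, and Rex2. By chromosome, 32 of 103 zinc finger genes on chromosome 7 had a peak, 20 of 42 on chromosome 13, 17 of 48 on chromosome 17, 14 of 33 on chromosome 4 and 14 of 20 on chromosome 9. Windows of 2 kb on each side of the transcription start held a replicated peak in only 18 members, and the excess was then not past the threshold (2.24-fold, adjusted two-sided permutation p = 0.12).

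Within zinc finger genes peaks lay on the last exon more often than on the first. The last exon is the one that in KRAB zinc finger genes codes for the zinc finger array. Of the 153 genes with a peak, all with at least 2 exons, 110 (71.9%) had one on the last exon and 4 on the first exon. In 107 genes the last exon alone was overlapped and in 1 gene the first exon alone (two-sided exact McNemar p = 6.72e-31). Last exons are longer, with a median of 2483 bp against 122 bp, so covered bases were compared too. Replicated peaks covered 33.2% of last-exon bases, 2.80% of first-exon bases and 5.05% of intron bases of these genes. In replicate 1 and replicate 2 alone, over the genes marked in each, last exons were covered to 21.5% and 25.3%, first exons to 0.902% and 1.77%, and introns to 2.69% and 3.28%. Peaks were not confined to the last exon, and of the 4 genes named above the strongest peak lay mostly in an intron in Zfp873 and Zfp110 and in annotated promoter sequence in Zfp930. Many of these genes are neighbours in clusters and are not independent, so the exact p is too small.

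Clustered protocadherins, cell-surface proteins of neurons encoded in tandem on chromosome 18, had the highest share of marked genes of the 22 lists. A replicated peak lay in 48 of 56 (85.7%), against 19.9% after rotation (4.30-fold, adjusted two-sided permutation p = 0.0044), and 92.9% ± 2.53 had a peak in the replicate lists (SD, n = 2). The excess was smaller there, 2.18-fold in replicate 1, 2.51-fold in replicate 2 and 1.92-fold in the pooled list. Pcdhga1 (ENSMUSG00000103144.1, 37661793 to 37841873) held 68 replicated peaks, with 64.2 kb ± 5.69 of peak bases in the replicate lists (SD, n = 2). Pcdhga2 held 62.8 kb ± 5.84, Pcdhga3 61.3 kb ± 5.74 and Pcdhgb1 57.9 kb ± 5.34 (SD, n = 2 for each). These genes share their 3′ exons and lie inside one another, so a peak was counted in several of them, and their 48 marked members hold 141 distinct peaks. The 8 members without a replicated peak included Pcdhgc3, Pcdhgc4 and Pcdhgc5, which end where the other Pcdhg genes end. Pcdhac1 and Pcdhac2, at the 3′ end of the Pcdha genes, had none either. The peaks counted several times therefore lay upstream of this shared 3′ part, not in it. The named genes include the 25 with the most bases of replicated peaks that were also overlapped in each replicate list. Of these 25, 17 were Pcdhg genes and so not independent. They ran from Pcdhga1 with 78.5 kb to Pcdhga11 with 14.9 kb of such replicated peaks. The members form 2 loci when genes within 100 kb are joined, a setting chosen after the data were examined, and both had a peak (adjusted two-sided permutation p = 1), so the excess rests on members of 1 region.

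**Figure D4:**
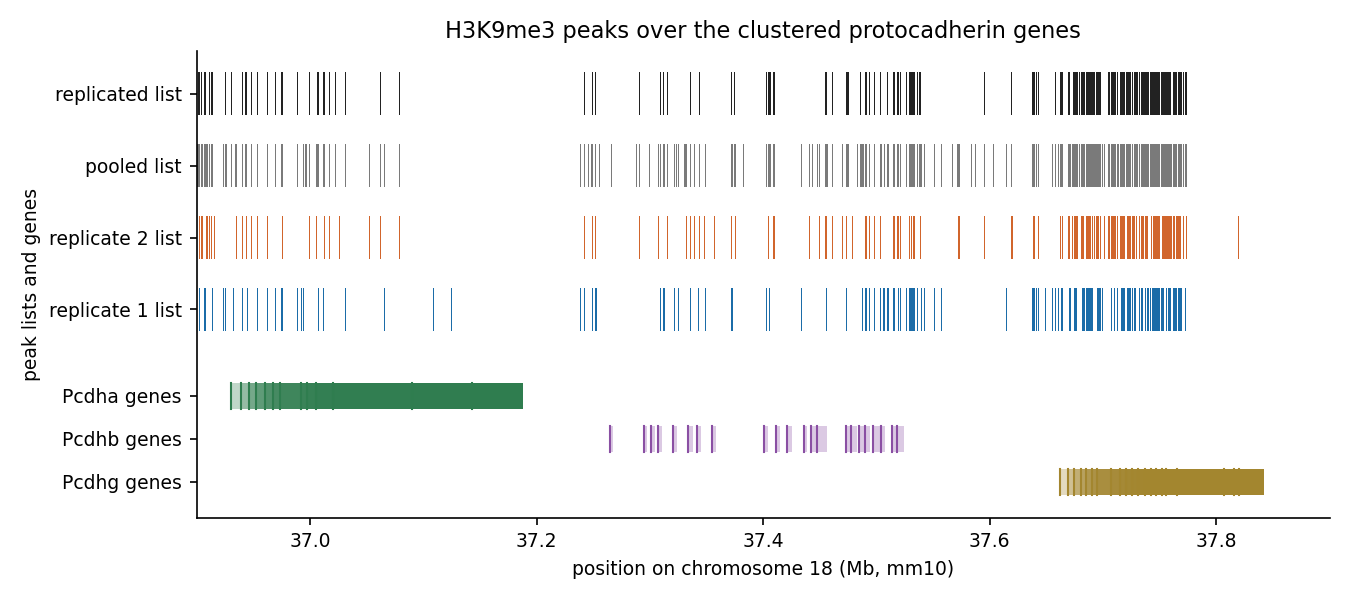
Map of chromosome 18 from 36.9 to 37.9 Mb (x axis, mm10) with the peaks of the replicated, pooled, replicate 2 and replicate 1 lists as vertical marks, above the Pcdha, Pcdhb and Pcdhg genes as shaded spans with a line at each gene's left end. Peaks are densest over the variable 5′ part of the Pcdhg genes in all 4 lists.

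Vomeronasal receptors, which detect pheromones in the nose, were marked in 68 of 326 genes (20.9%), 3.45 times the mean of rotations (adjusted two-sided permutation p = 0.00293), and in 31.4% ± 1.08 of genes in the replicate lists (SD, n = 2). In replicate 1 alone the excess fell to 2.03-fold, in replicate 2 alone to 2.26-fold and in the pooled list to 1.77-fold. Vmn2r60 on chromosome 7 (42107770 to 42196208) held 13 replicated peaks and 6.26 kb ± 0.0368 of peak bases in the replicate lists, Vmn1r73 4.67 kb ± 0.0552, Vmn2r61 2.66 kb ± 0.148 and Vmn2r63 1.57 kb ± 0.0474 (SD, n = 2 for each). Vmn1r1 and Vmn1r10 had none. The excess was not past the threshold near transcription starts (19 genes, adjusted two-sided permutation p = 0.12) or with members within 100 kb joined into 83 loci (1.90-fold, adjusted two-sided permutation p = 0.0605). Olfactory receptors, a far larger family of sensory receptors, did not stand out, with a peak in 43 of 1092 (3.94%; adjusted two-sided permutation p = 1). Olfr943 held 2 replicated peaks, while Olfr1 and Olfr10 held none. Cytochrome P450 genes, enzymes of drug and steroid metabolism, had a peak in 18 of 93, 2.18-fold over rotations, which did not pass adjustment (two-sided permutation p = 0.027, adjusted 0.099). The excess was 1.51-fold in replicate 1 alone, 1.42-fold in replicate 2 alone and 1.30-fold in the pooled list. Cyp3a11 and Cyp3a16 on chromosome 5 held 7 replicated peaks each.

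Imprinted genes, expressed from one parental chromosome, had the highest excess of any list that passed. A replicated peak lay in 30 of 36 (83.3%), against 15.8% after rotation (5.28-fold, adjusted two-sided permutation p = 0.0022), and in 87.5% ± 1.96 in the replicate lists (SD, n = 2). Replicate 1 alone gave a 2.48-fold excess, replicate 2 alone 2.89-fold and the pooled list 2.20-fold. Some members are neighbours and so not independent. Members within 100 kb were joined into 23 loci, a setting chosen after the data were examined. Of these loci 19 had a peak, a 3.69-fold excess (adjusted two-sided permutation p = 0.0022). Gnas, on chromosome 2 (174284320 to 174346744), held 7 replicated peaks and 6.99 kb ± 0.710 of peak bases in the replicate lists (SD, n = 2). Its strongest peak, at 174297742 to 174299763, overlapped an annotated promoter and had a fold enrichment of 8.0. The strongest peak of Mest, on chromosome 6 at 30737628 to 30739822, also lay mostly in promoter sequence, and that gene held 4.12 kb ± 0.0651 (SD, n = 2). Grb10 and Kcnq1 held 5.17 kb ± 0.658 and 5.21 kb ± 0.421 (SD, n = 2 for each), and the strongest peak of Kcnq1 lay in an intron.

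Germline genes, needed for meiosis and for silencing transposons in germ cells, had a replicated peak in 11 of 36 (30.6%), 2.55-fold over rotations (adjusted two-sided permutation p = 0.0246). Of these 36 genes, 9 had a peak within 2 kb of a transcription start (25% against 1.86% over rotations, adjusted two-sided permutation p = 0.00147). The peak of Dazl, an RNA-binding protein of germ cells, spanned chromosome 17 from 50293026 to 50294192 with its middle 0.028 kb from the start of the gene. Single promoter peaks also marked Ddx4, Taf7l and Meioc. Peak bases in the replicate lists came to 1.04 kb ± 0.395 for Dazl, 0.357 kb ± 0.108 for Ddx4, 0.949 kb ± 0.110 for Taf7l and 0.761 kb ± 0.315 for Meioc (SD, n = 2 for each). Asz1 and Tdrkh had no replicated peak. In each replicate list alone, 45.8% ± 1.96 of germline genes had a peak (SD, n = 2), but the excess over rotations was not past the threshold (1.62-fold and 1.75-fold, adjusted two-sided permutation p = 0.11 and 0.0557).

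None of the lists of kidney genes differed from rotations. Rotations gave means of only 1.62 to 3.64 genes for them. For the endothelial, blood, neural, other lineage, pluripotency and housekeeping lists the means were 1.18 to 2.69. Fewer marked genes could therefore hardly have been detected in any of these lists. Nephron progenitor genes had a peak in 1 of 15, ureteric bud and collecting duct genes in 1 of 19, nephron tubule and podocyte genes in 3 of 21, and kidney stroma genes in 2 of 15 (adjusted two-sided permutation p = 1 for each). In the replicate lists the shares were 20.0% ± 9.43, 13.2% ± 3.72, 28.6% ± 6.73 and 16.7% ± 4.71 in that order (SD, n = 2 for each). Six2, which keeps nephron progenitors undifferentiated, and Cited1 had no replicated peak, and neither did Ret and Wnt11 of the ureteric bud, Lhx1 and Jag1 of the forming nephron, or Foxd1 and Pdgfra of the stroma. The exceptions included Tmem100, Gfra1, Ptpro, Magi2 and Pdgfrb, with 1 to 4 replicated peaks each. Endothelial genes had a peak in 2 of 14 and neural lineage genes in 1 of 20. Blood and macrophage genes, and liver, gut, muscle and skin genes, had none of 20 and none of 24, so Ptprc, Csf1r, Alb and Afp held no replicated peak. Pluripotency and 2-cell genes had a peak in 2 of 34, Duxf3 and Esrrb, but not in Pou5f1 or Nanog. Among cell cycle and housekeeping genes 1 of 20 had a peak, Tbp, and Actb and Gapdh had none. The adjusted two-sided permutation p was 0.95 for neural lineage genes and 1 for the other 5 lists.

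Several other tandem families held no replicated peak. No replicated peak lay in the 39 Hox genes, the 67 replication-dependent histone genes, the 34 genes of the Rhox cluster or the 26 kallikreins, but rotations gave means of only 0.821 to 1.56 genes for these lists, so fewer could not have been detected (adjusted two-sided permutation p = 1 for each). Serpins had 1 marked gene of 61 against a mean of 4.39 (adjusted two-sided permutation p = 0.696). The serpin value rested on 1 pool, since 10 of 61 had a peak in replicate 1 and 1 of 61 in replicate 2, and replicate 2 alone gave an adjusted two-sided permutation p of 0.0211 for fewer genes.

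Of the 10 most covered 1-Mb windows, 6 held members of a list that passed and 4 held none, and of the 10 longest runs of peaks 2 overlapped such a member, which was not tested against random placement. Among the windows, the window of chromosome 18 from 37000001 to 38000000, which overlaps all 56 clustered protocadherins, ranked first, with 163 replicated peaks over 14.0% of its bases and 11.7% ± 0.665 in the replicate lists (SD, n = 2). In the replicated list it was followed by a window of chromosome 10 (82000001 to 83000000, with Zfp873 and AU041133) at 7.76%. A window of chromosome 4 (147000001 to 148000000, with 10 zinc finger genes) came next at 7.59%. In the replicate lists these windows held 6.52% ± 0.565 and 6.65% ± 0.391 (SD, n = 2), in the same order. On chromosome 7, a window with secretoglobin genes such as Scgb2b24 (33000001 to 34000000) and one with Ceacam and Psg genes of the carcinoembryonic antigen family (17000001 to 18000000) held 6.34% ± 0.0455 and 5.98% ± 0.106 (SD, n = 2). A window of chromosome 1 (88000001 to 89000000) with Mroh2a, Trpm8, a cold-sensing channel, and Ugt1a genes, which conjugate bilirubin and drugs, held 5.97% ± 0.363 (SD, n = 2). The window of chromosome 12 from 114000001 to 115000000, in the variable part of the immunoglobulin heavy chain locus, has no protein-coding gene annotated and held 6.63% ± 0.00431 (SD, n = 2). Of 2660 windows, 516 had no replicated peak, and the 27 most covered held 20.4% of all replicated peak bases. With peaks within 5 kb merged, the longest run spanned 121.1 kb over the Pcdhg genes (chromosome 18, 37656660 to 37777758), with 70 peaks, and the next spanned 55.8 kb at Ceacam11 (chromosome 7, 17940137 to 17995960).

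The single replicated peak of highest fold enrichment lay on Klf14, a transcription factor gene without introns, on chromosome 6 from 30955991 to 30958761. Its fold enrichment was 13.3 in the replicated list, and the overlapping peaks of replicates 1 and 2 had 11.1 and 11.2. The next highest was at the promoter of Tcfl5 on chromosome 2 (180642720 to 180643564), at 9.87, and another lay 15434 bp from Ptprs on chromosome 17 (56491918 to 56495319), at 9.46. Others in the top 10 overlapped exons of Zfp850, Pcdhga10 and Pcdhgb7, and an exon and mostly intron sequence of Asmt, the last enzyme of melatonin synthesis, on the X chromosome. The intergenic peak on chromosome 7 at 12011194 to 12012730 and the one on the Y chromosome at 259023 to 259448 had 57.0% and 42.5% of their 32-bp words found once in the assembled chromosomes (the rest occurred more than once).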

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

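Replicated peaks also lay outside the analysed chromosomes. On scaffolds that the mm10 assembly leaves unlocalized or unplaced, 255 of the 14160 replicated peaks (1.80%) were found, on 23 scaffolds, and they were singled out because they were left out of the overlap, chromosome, annotation and gene list tests. The replicate lists held 361 and 370 such peaks (365.5 ± 6.36, SD, n = 2). Median fold enrichment of these replicated peaks was 3.63, against 3.55 over the whole list, and their median length was 552 bp against 423 bp. The scaffold with the most held 71. No peak of any list lay on the mitochondrial chromosome.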

How the results depend on the processing

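All overlap tests of the replicate lists, the rank correlation of chromosomes, and the exon, intron and last-exon results kept their direction and their side of the threshold under each alternative run. For shared bases the 50% overlap rule was no alternative, since it does not enter their count and could not change them. Shared bases ran from 13.2 to 18.7%, and the last-exon difference from 62.1 to 69.3 percentage points. The excess of shared bases over random placement ran from 61.7-fold (shuffling within chromosomes) to 129-fold (the 20000 peaks of highest −log10 p) and 155-fold (q of at most 0.05). These stricter lists did not raise the share of overlapped peaks in both directions. It was 25.6% and 24.9% with the 20000 peaks, and 29.5% and 21.2% with q of at most 0.05 (replicate 1 first). The main setting gave 25.7% and 27.8%. Both lists were filtered, so partner peaks were lost too. Of the values that answer a comparison, 95 kept their side of the threshold or, without a test, stayed within the spread or counted as unchanged. Another 20 moved, 3 newly passed a threshold and 6 no longer passed it, and none changed direction past a threshold. The 95 include promoter shares that changed direction without passing, given below. They also include the number of gene lists that passed, 5 in the main setting, where it was 4 or 6. The excess itself could change greatly: without one replicate it was 2.06 to 2.30 for zinc finger genes, 2.03 to 2.26 for vomeronasal receptors, 2.18 to 2.51 for protocadherins and 2.48 to 2.89 for imprinted genes, near transcription starts 44.0 and 20.9 for the last pair, and with at least 500 bp of peak 6.04 for zinc finger genes, 6.59 for protocadherins and 7.99 for imprinted genes. Of the other gene lists' values, 151 kept their side and 2 newly passed, cytochrome P450 genes against length-matched genes (2.10-fold, adjusted permutation p = 0.0114, but 1.42 to 1.51 without one replicate) and serpins without replicate 1. A 1 bp overlap put 14.9% of pooled peaks in both replicate lists. Chromosome 7 coverage was 2.48 times the genome's with peaks of q at most 0.05, 2.43 by peaks per Mb, 2.31 in the pooled list, and 2.15 to 2.17 without one replicate. Chromosome 17 was at 1.92 in the pooled list and 1.86 to 1.94 without one replicate. X was at 0.240 in the main setting, 0.373 in the pooled list and 0.349 to 0.457 without one replicate. The intergenic share passed at 1.09 with midpoints and at 1.07 to 1.08 without one replicate. The promoter share was 1.14 in the main setting but 0.863 with midpoints and 0.945 in each replicate list alone, none past the threshold. Near transcription starts 3 gene lists passed, with zinc finger genes at 2.24 and vomeronasal receptors at 3.09, both lost. With members within 100 kb joined, chosen after the data were examined, also 3 passed, with vomeronasal receptors at 1.90 and protocadherins at 2.08 lost, the latter because only 2 loci remained. Germline genes lost their call at 1.62 to 1.75 without one replicate. Lists with fewer marked genes ran from 0 to 1 without one replicate. An overlap of 50% lowered the top deciles to 48.5% and 50.3%. Windows of 500 kb raised the highest coverage to 20.7%, and merging gaps of 1 and 10 kb gave longest runs of 45.1 and 234 kb, which follows from the window and gap sizes. Apart from these the cause was not tested. The single-list alternatives gave no rank correlation, which needs both replicates. Unknown depth limits what a missing peak shows.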

Other observations

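The tests of nearby peaks, of deciles by −log10 p and of Y chromosome peaks, the weighing of all peak subsets for the X chromosome, and the choice of the non-coding transcripts below came only after the results were seen. Imprinted transcripts that do not code for protein, left out of the tested list for that reason, held a replicated peak in 5 of 6 cases, but most of these peaks were already counted for coding genes of that list. Shared were 8 of 8 peaks of Kcnq1ot1 with Kcnq1, 4 of 4 of Nespas with Gnas, 2 of 2 of Peg13 with Trappc9 and 3 of 9 of Airn with Igf2r, and none of Meg3. Airn, which silences Igf2r on chromosome 17, held 9 replicated peaks and 7216 bp ± 83.4 of peak bases in the replicate lists (SD, n = 2), the strongest at 12740965 to 12743644. Kcnq1ot1 on chromosome 7 held 8 peaks and 4560 bp ± 725, Nespas on chromosome 2 held 4 and 3574 bp ± 115, Meg3 on chromosome 12 held 3 and 1858 bp ± 511, and Peg13 on chromosome 15 held 2 and 2404 bp ± 933 (SD, n = 2 for each). H19 on chromosome 7 (142575529 to 142578143) held none in the replicated list or in either replicate list. Sequence more than 1 kb from a gene was not counted, so this does not describe the rest of the H19 locus.

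Called peak sequence was not richer in masked repeats than the assembled chromosomes, which was not tested against rotations. How reads that match several places were handled is not stated. The shares below therefore do not show how much of the mark lay on repeats. Bases masked as repeats made up 33.2% ± 0.882 of the replicate lists (SD, n = 2) and 36.4% of the assembled chromosomes. GC content was 45.2% ± 0.350 against 41.7%, and CpG sites numbered 0.983 ± 0.00434 per 100 bp against 0.826 (SD, n = 2). In replicated peaks 91.3% of 32-bp words occurred once in the assembled chromosomes, against 83.5% at a random rotation of the same peaks.

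Most peaks of one replicate had no overlap in the other. Counting noise at weak peaks is a candidate explanation. Ranked by fold enrichment, the top decile was overlapped 2.43 and 2.27 times as often as the lowest, between the bounds of 1.5 and 3 set beforehand, and ranked by −log10 p it was 4.12 and 3.24 times as often, past the upper bound in both (replicate 1 first). The second ranking was added after the results were seen. It goes with counting noise as part of the cause but does not single it out. Peaks near the calling threshold could recur less under other causes too. The first ranking leaves the extent of counting noise open. Of the 1000 peaks of highest −log10 p, 17.4% in replicate 1 and 16.7% in replicate 2 had no overlap, above the 10% set beforehand for sites marked in only 1 pool. That explanation was put back to undecided after the nearby peaks were seen, and cannot be told apart from missed calls, since 66.1% and 68.9% of those peaks lay within 5 kb of a peak of the other replicate, where no rotation exceeded 20.7% and 18.6%. Shared stretches cut into pieces at different places may therefore account for much of the non-overlap of strong peaks, as a hypothesis.

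X chromosome coverage was lower in replicate 2. Its 806 X peaks against 1180 in replicate 1 were 0.753 times what the autosomes gave. This sets 1 list against 1 list, so the spread between pools is not known and no difference between the pools can be claimed from it. Whether weak peaks near the calling threshold carry the difference stays open, since stricter peak sets disagreed. Among the 10000 peaks of highest −log10 p of each replicate, X coverage in replicate 2 over replicate 1 was 0.902, within the autosomes' range of 0.865 to 1.47, but X peak counts relative to autosomes were 0.796, near the value over all peaks and with fewer peaks to count. Among the top 20000, X coverage in replicate 2 was higher, 1.18 times that in replicate 1, and relative counts were 1.23. Among peaks with q of at most 0.05, relative counts were 0.928 and the coverage ratio, 1.20, lay below that of the lowest autosome, 1.26. A different share of males in the pools could not be tested well, since Y peaks numbered 15 and 18, a ratio of 1.2, with a coverage ratio of 1.69, and it stays open.

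Tandem families can share reads between near-identical copies, which could produce peaks. With only replicated peaks of at least 90% unique 32-bp words, a peak still lay in 124 zinc finger genes (adjusted permutation p = 0.00147), 50 vomeronasal receptors (adjusted permutation p = 0.0077) and 46 clustered protocadherins (adjusted permutation p = 0.00147). These values argue against reads shared between identical copies on the assembled chromosomes as the whole cause in the 3 families. This holds only if reads were at least as long as these words, which is not known here. Copies that differ by a base or lie on other scaffolds were not covered, so for those the question stays open. No biological explanation was tested, as the design has 1 group.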
